A study of Homo sapiens with 16 samples.

How the data were processed

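RNA of 8 cell populations was measured, with 2 libraries per population and 16 libraries in all. The populations are the parental cells and 3 venetoclax-resistant clones of each of 2 human myeloma cell lines with t(11;14), KMS12PE (clones A, C and D, replicates 1 and 3) and KMS27 (clones B5, C1 and C5, replicates 1 and 2). Per the labels' protocols, the cells were grown in RPMI-1640 with serum, the clones were kept in 100 nM venetoclax, DNA and RNA were taken with AllPrep, and poly-A RNA libraries were made from 200 ng of RNA with the Roche Kapa mRNA HyperPrep kit. The dose given to the parental cells is not stated, so the change of clones against parental cells holds the drug, the selection and the single-cell origin together. Whole-genome sequencing of the series was not used here.

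The authors deposited 1 table of counts per gene symbol for each cell line, with 1 column per library. Reads were mapped to hg38 per the submitters' processing notes, and the aligner, the counting tool, the annotation and the strandedness are not given in the sources used here. The values are whole numbers with totals that differ between libraries, so they were taken as counts without normalization. In KMS12PE 12592 genes are listed and in KMS27 14560, of which 11623 are in both. Every gene listed has at least 5 counts in at least 4 of the 8 libraries of its line, a filter found from the values and stated nowhere, so genes silent in most populations are missing. No mitochondrially encoded gene is listed, BCL2A1 and FCRL5 are in neither table, and GPRC5D is in the KMS12PE table alone.

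Total counts ran from 5831289 to 13674426 in KMS12PE and from 20257318 to 52615971 in KMS27. The KMS12PE parental libraries were the smallest of their line (5831289 and 6340658 counts). In KMS12PE 3 counts corresponded to 0.219 to 0.514 CPM and in KMS27 to 0.0570 to 0.148 CPM. Where a population had 0 counts over its 2 libraries, a fold is given as a lower bound against 3 counts over the population, and with 1 to 3 counts as a ratio with its exact 95% interval. These floors and intervals cover counting error only. With such genes at their bound no list median moved by more than 0.0065.

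Each cell line was fitted on its own with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr (12279 in KMS12PE and 14088 in KMS27, leaving out 313 and 472), libraries were scaled with TMM, dispersions were estimated with estimateDisp, and a quasi-likelihood model with 1 mean per population was fitted with glmQLFit and tested with glmQLFTest, 2-sided. The biological coefficient of variation was 11.9% in KMS12PE and 14.3% in KMS27. The contrasts were the mean of the 3 clones minus parental, each clone minus parental, a joint test among the 3 clones, and each population against the mean of the other 3. A gene counts as changed in all 3 clones when each clone passed on its own with 1 sign. A joint fit of the 16 libraries over the genes in both tables tested the difference between the 2 lines in the response, KMS12PE minus KMS27. P-values were adjusted with Benjamini-Hochberg over all genes tested and called under 0.05. Overlaps between lines were set against independence with Fisher's exact test across genes.

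38 gene lists were written from general knowledge of myeloma and its drugs. They were tested with camera (limma 3.58.1) at its preset correlation of 0.01 on log2 CPM with a prior count of 2, with an estimated correlation as an alternative, and adjusted over the lists with 3 or more tested genes (35 in KMS12PE and 34 in KMS27). None of the 13 calls, nor any of the 9 list differences between lines, passed with an estimated correlation. Fry, also from limma and planned, was run beside camera. It tests the genes of a list without comparing them with other genes. List p-values are from camera unless fry is named. Symbols were matched to GENCODE v29 for 11659 and 12721 genes, and the genes of each chromosome were tested with camera in each clone, with medians in windows of 20 Mb that hold 20 or more genes.

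The main comparisons, their tests, the lists, most alternatives and the rule for named genes were fixed before the data were examined. Tests and alternatives chosen later are marked as such where they are given. The rule names, per line, the 10 genes with the largest rise and the 10 with the largest fall among those called in all 3 clones at a mean of at least 3 log2 CPM, a fixed set of BCL2 family, antigen and cereblon genes whatever their result, up to 4 called genes of each list with the smallest adjusted p, and up to 6 genes with opposite signs in the lines. The exceptions, named after their values were seen, are PTPRK and ETS1 in KMS12PE, the genes changed in both lines, and the genes at least 16-fold lower in a clone.

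The planned fit did not use replicate number as a block. In KMS12PE libraries with 1 number resembled each other across populations (correlations of the paired differences 0.254 to 0.537), and in KMS27 they did so less (0.0597 to 0.444), so values with the block are given for several KMS12PE results. The 2 libraries of a population differed by more than counting error (chi-square per degree of freedom 5.19 to 58.0), so none is a copy of another. The models were tested on simulated data, negative binomial counts with changes of known size. Of genes changed 2-fold, 65.7% were recovered in KMS12PE and 61.2% in KMS27, of those changed 4-fold 87.9% and 90.9%, and of those changed 1.5-fold 44.8% and 26.9%. Of unchanged genes 6 of 12079 and 12 of 13888 were called. The inserted list and the inserted chromosome shift were each recovered in both lines, with 0 false calls. Genes were simulated independently of each other, so false calls of these 2 tests among correlated genes were not checked.

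The 3 clones of a line share the parental libraries, which makes their changes alike even with no effect. In 20 simulated draws without an effect 0.15 genes in KMS12PE and 0.05 in KMS27 were called in all 3 clones on average. With 2 parental libraries the controls cannot be split among the clones.

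The alternatives were RLE scaling, library totals alone, no filter, a stricter filter, DESeq2 1.42.0 and the block. Others were immunoglobulin genes and JCHAIN left out, thinning to the smallest total, and leaving out each library and each clone. The last were a 2-fold threshold and 3 fits that count the spread between clones as error. Of these 3 fits, 2 have the clone as the unit, with the libraries of each clone summed or limma-voom with the population as a random block. In the summed fit the 2 parental libraries stayed separate, so it sets 3 clones against 2 libraries of 1 population. The third ignores clone identity and treats the 6 clone libraries as independent replicates. Lists were tested without the random block, so for them limma-voom repeats the third. Leaving out 1 library leaves 1 population with a single library, which is then assumed to vary like the others. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.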

Results

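The deposited RNA counts compare 3 venetoclax-resistant clones with the parental population in each of 2 myeloma cell lines that carry t(11;14), KMS12PE (clones A, C and D) and KMS27 (clones B5, C1 and C5). The clones were grown from single cells that persisted under high-dose venetoclax, an inhibitor of the survival protein BCL2, and were kept in 100 nM of the drug. Each population has 2 libraries. Levels are CPM, each gene's counts scaled to the TMM-normalised library total. They are given as mean ± SD over 2 libraries for a parental population and over 3 clone means for the clones. Log2 fold changes (log2FC) are the mean of the 3 clones minus parental unless a clone is named.

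In KMS27 the antigen-presentation genes of MHC class II, which display peptides to CD4 T cells, were far more abundant in the resistant clones. HLA-DRA, the alpha chain of HLA-DR, rose from 160.02 ± 24 CPM to 1663 ± 491 CPM (log2FC 3.34, adjusted p = 1.25e-05). HLA-DPB1, a beta chain of HLA-DP, rose from 15.5 ± 0.72 CPM to 144 ± 37 CPM (log2FC 3.18, adjusted p = 8.44e-06), and CD74, a chaperone of class II molecules, rose from 669 ± 40 CPM to 2272 ± 499 CPM (log2FC 1.74, adjusted p = 0.000128). Each of these genes was above both parental libraries in 6 of 6 clone libraries. HLA-DQA1 and HLA-DRB1 rose by log2FC 3.31 and 3.26, although reads shared between HLA-DRB1 and HLA-DRB5, and between HLA-DQA1 and HLA-DQA2, make the split within each pair uncertain. Over the 16 class II genes tested, 14 were higher and 0 lower over all genes, 15 and 0 when adjusted over the list alone, and 13 were higher in each of the 3 clones. The median log2FC was 2.66, with 2.26 in clone B5, 2.62 in clone C1 and 3.28 in clone C5. The list test gave adjusted p = 2.59e-12, and adjusted p = 0.819 with an estimated correlation between the genes. In KMS12PE the same list had a median log2FC of -0.14 (adjusted p = 0.259). The difference between the lines was tested directly, and 15 of 16 genes differed (adjusted p = 5.59e-20, and adjusted p = 0.133 with an estimated correlation). The 1 gene called in KMS12PE was CTSS, the cathepsin that trims CD74 (log2FC -0.80, adjusted p = 0.00748), while 1 was higher and 2 lower when adjusted over the list alone. Without parental replicate 3 its adjusted p was 0.163, and without parental replicate 1 it was 0.0777.

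**Figure D1:**
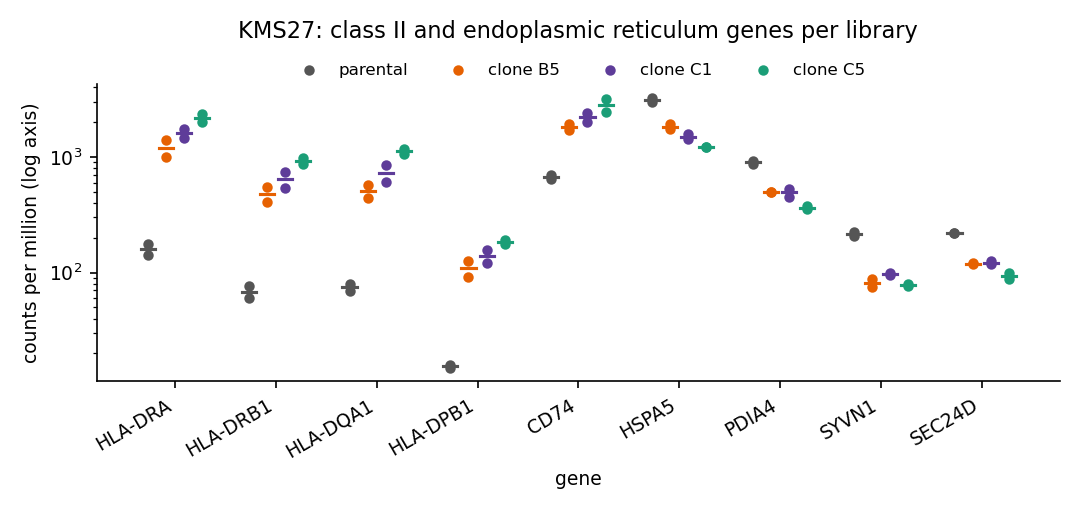
CPM (log axis) of 5 class II genes and 4 endoplasmic reticulum genes in KMS27, with 1 point per library (2 per population) and a bar at the mean of each population. For each of the 5 class II genes all 6 clone libraries lie above both parental libraries, and for each of the 4 endoplasmic reticulum genes all 6 lie below.

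MHC class I presentation did not move as a list in KMS27 (20 genes, median log2FC 0.20, adjusted p = 0.366), with 7 genes higher and 4 lower (9 and 4 when adjusted over the list alone). TAP1, which pumps peptides into the endoplasmic reticulum, rose from 49.8 ± 7.9 CPM to 102 ± 25 CPM (log2FC 1.01, adjusted p = 0.00121), and the heavy chain HLA-B rose from 796 ± 59 CPM to 1516 ± 155 CPM (log2FC 0.92, adjusted p = 0.00165), each in 6 of 6 clone libraries. Interferon-stimulated genes did not rise as a list. Of 30 tested, 2 were higher and 11 lower, with the same counts when adjusted over the list alone, at a median log2FC of -0.38 (adjusted p = 0.0522). Clone B5 alone passed, with medians of -0.66 in B5 (adjusted p = 1.10e-05), -0.35 in C1 (adjusted p = 0.0616) and 0.26 in C5 (adjusted p = 0.435). SAMD9L, an interferon-induced growth inhibitor, fell from 188 ± 14 CPM to 82.1 ± 12 CPM (log2FC -1.20, adjusted p = 0.000971), whereas the chemokine CXCL10 rose from 0.268 ± 0.17 CPM to 4.99 ± 4.3 CPM (log2FC 3.87, adjusted p = 0.000223).

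Genes of the unfolded protein response and of secretory protein folding fell in the KMS27 clones. HSPA5, the main chaperone of the endoplasmic reticulum, fell from 3118 ± 205 CPM to 1517 ± 300.0 CPM (log2FC -1.06, adjusted p = 0.000268). PDIA4, which forms disulfide bonds, fell from 897 ± 37 CPM to 452 ± 75 CPM (adjusted p = 0.000188), and SYVN1, the ubiquitin ligase that removes misfolded proteins, fell from 214 ± 12 CPM to 85.6 ± 11 CPM (log2FC -1.33, adjusted p = 1.81e-05). All 3 were below both parental libraries in 6 of 6 clone libraries. Of the 30 genes of the list, 22 were lower and 1 higher over all genes, and 24 and 2 when adjusted over the list alone. The median log2FC was -0.70 (adjusted p = 1.46e-09, and adjusted p = 0.819 with an estimated correlation), and 15 genes were lower in each of the 3 clones. In KMS12PE the list moved the same way by less (29 genes, median log2FC -0.12, adjusted p = 0.00986, and adjusted p = 0.977 with an estimated correlation). By clone its adjusted p was 0.0119 in A, 0.00142 in C and 0.392 in D. There 1 gene was lower, also when adjusted over the list alone, and it was HERPUD1. This partner of SYVN1 went from 102 ± 0.52 CPM to 72.1 ± 11 CPM (log2FC -0.51, adjusted p = 0.00684), and its adjusted p was 0.0991 without parental replicate 3 and 0.0975 without parental replicate 1. The list's own adjusted p in KMS12PE was 0.0632 without clone A replicate 3, 0.0547 without clone C replicate 3, 0.0501 without clone D replicate 3 and 0.117 without parental replicate 3. The responses of the lines differed for this list (13 of 29 genes, adjusted p = 3.22e-08, and adjusted p = 0.444 with an estimated correlation).

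Plasma cell genes fell with them in KMS27. MZB1, a chaperone of immunoglobulin assembly, fell from 269 ± 5.0 CPM to 129 ± 23 CPM (log2FC -1.08, adjusted p = 0.000124), and the folding enzyme FKBP11 fell from 140 ± 6.7 CPM to 73.2 ± 12 CPM (adjusted p = 0.000212), both in 6 of 6 clone libraries. Of 22 plasma cell genes 7 were lower and 0 higher, 11 and 0 when adjusted over the list alone (median log2FC -0.26, adjusted p = 0.000114, and adjusted p = 0.975 with an estimated correlation). By clone the adjusted p was 0.00945 in B5, 0.186 in C1 and 1.02e-08 in C5. Immunoglobulin genes, counted together with JCHAIN, took 4.58% and 5.02% of the counts of the parental libraries and 2.18% to 3.55% of those of the clones. B cell genes moved apart from each other. The kinase BTK rose from 14.7 ± 0.76 CPM to 51.4 ± 9.8 CPM (adjusted p = 7.82e-06), while the tetraspanin CD37 fell from 9.38 ± 0.24 CPM to 0.231 ± 0.041 CPM (log2FC -5.33, adjusted p = 1.84e-06) and the kinase BLK from 13.2 ± 0.55 CPM to 1.45 ± 0.56 CPM (log2FC -3.26, adjusted p = 9.59e-06). Of the 17 genes of that list 4 were higher and 4 lower, or 7 and 4 when adjusted over the list alone, and its adjusted p was 0.496.

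Proliferation genes were higher in KMS27 clones B5 and C5. POLA1, a subunit of the polymerase that starts DNA synthesis, rose from 96.7 ± 0.16 CPM to 190 ± 25 CPM (log2FC 0.97, adjusted p = 0.000217) and the cyclin CCNE2 from 27.9 ± 1.5 CPM to 51.2 ± 11 CPM (log2FC 0.85, adjusted p = 0.000753), both in 6 of 6 clone libraries. RRM2, which makes deoxyribonucleotides, had log2FC 2.15 in clone B5, 0.72 in C1 and 0.62 in C5. Of 35 S-phase genes 15 were higher and 1 lower, 18 and 1 when adjusted over the list alone (median log2FC 0.29, adjusted p = 9.45e-05, and adjusted p = 0.975 with an estimated correlation). Of 35 G2/M genes 13 were higher and 0 lower, with the same counts when adjusted over the list alone (median log2FC 0.24, adjusted p = 0.000109, and adjusted p = 0.819 with an estimated correlation). Clone C1 alone gave adjusted p = 0.186 for the S-phase list and 0.823 for the G2/M list, and without clone B5 the G2/M list had adjusted p = 0.0692. In the same clones ribosomal protein genes were lower (adjusted p = 0.0244 in B5 and 3.75e-05 in C5), and histone genes were higher in C5 (median log2FC 0.85, adjusted p = 0.000555). The 2 libraries of B5 differed from each other, with 6.93% and 9.56% of their counts in ribosomal protein genes. As a list, cholesterol synthesis genes lay higher in KMS27 and lower in KMS12PE, and in each line 1 clone passed alone. In KMS27 NSDHL, a late enzyme of the pathway, went from 16.2 ± 2.2 CPM to 30.8 ± 1.9 CPM (log2FC 0.93, adjusted p = 0.00392, and 0.0585 without parental replicate 1). Of 24 genes 7 were higher and 0 lower, with the same counts when adjusted over the list alone. The list had a median log2FC of 0.24 (adjusted p = 0.0369, and adjusted p = 0.975 with an estimated correlation). By clone the median was 0.42 in B5 (adjusted p = 7.11e-05), 0.20 in C1 (adjusted p = 0.366) and 0.08 in C5 (adjusted p = 0.447). The adjusted p of the list was 0.124 without parental replicate 1, 0.120 without clone C5 replicate 2 and 0.227 without the genes of chromosomes 4, 6, 8, 11 and X, whose genes shifted together. In KMS12PE the median was -0.16 (adjusted p = 0.00986, and adjusted p = 0.868 with an estimated correlation), with 0 genes called over all genes and 6 lower when adjusted over the list alone. By clone it was -0.24 in A (adjusted p = 5.93e-06), -0.04 in C (adjusted p = 0.636) and -0.16 in D (adjusted p = 0.139). That list gave adjusted p = 0.0603 without clone A replicate 3, 0.0501 without clone D replicate 3 and 0.209 without parental replicate 1. The responses of the lines differed for the S-phase list (adjusted p = 8.11e-05), the G2/M list (adjusted p = 1.08e-05) and the cholesterol list (adjusted p = 0.00220). With an estimated correlation these were 0.444, 0.444 and 0.561.

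The BCL2 family is the direct pathway of the drug, and 2 of its genes, BCL2L11 and PMAIP1, responded differently in the lines. In KMS27 BCL2L11, which encodes the death activator BIM, rose from 12.8 ± 0.15 CPM to 34.7 ± 17 CPM (log2FC 1.34, adjusted p = 0.000137), by 0.88 in clone B5, 1.06 in C1 and 2.08 in C5, in 6 of 6 clone libraries. BMF, a death activator released by stress, went from 254 ± 0.11 CPM to 190 ± 8.7 CPM (log2FC -0.42, adjusted p = 0.00706, with 0.0976 without parental replicate 1 and 0.0815 without parental replicate 2). In KMS12PE PMAIP1, which encodes NOXA, the antagonist of MCL1, went from 54.0 ± 1.4 CPM to 29.9 ± 7.0 CPM (log2FC -0.88, adjusted p = 0.00227), below both parental libraries in 6 of 6 clone libraries, with adjusted p = 0.0547 without parental replicate 3. The responses differed between the lines for BCL2L11 (adjusted p = 3.02e-05, with KMS12PE at log2FC 0.06) and for PMAIP1 (adjusted p = 4.55e-05, with KMS27 at log2FC 0.22). BCL2 itself had log2FC 0.17 in KMS12PE (adjusted p = 0.478) and 0.24 in KMS27 (adjusted p = 0.0799), but its clones differed. It was higher in KMS12PE clone C (log2FC 0.48, adjusted p = 0.0363), with 0.21 in D and -0.18 in A (adjusted p = 0.00559 among the clones). In KMS27 it was higher in clone C1 (log2FC 0.46, adjusted p = 0.0167), with 0.27 in C5 and -0.01 in B5 (adjusted p = 0.0439 among the clones). MCL1 had 0.18 (adjusted p = 0.405) and 0.13 (adjusted p = 0.346), and BCL2L1, which encodes BCL-XL, 0.32 (adjusted p = 0.416) and 0.43 (adjusted p = 0.0653, with 0.62 and adjusted p = 0.0367 in clone C1). As a list the 4 anti-apoptotic genes of KMS12PE lay slightly higher (median log2FC 0.18, adjusted p = 0.0456, and adjusted p = 0.801 with an estimated correlation). Over all genes 0 of the 4 were called, and 0 when adjusted over the list alone. The list passed in 0 of the 3 clones taken singly. In KMS27 the same list had a like median of 0.19 (adjusted p = 0.408), with 0 genes called over all genes and 2 higher when adjusted over the list alone. Its response did not pass a test of a difference between the lines (adjusted p = 0.974, 0 of 4 genes). The pro-apoptotic list had adjusted p = 0.990 in KMS12PE (0 higher and 1 lower of 10, the same when adjusted over the list alone) and 0.865 in KMS27 (1 higher and 2 lower of 10, 4 and 2 when adjusted over the list alone). Between the lines it had adjusted p = 0.642, with 0 of 9 genes higher and 2 lower in KMS12PE relative to KMS27, and 1 and 3 when adjusted over the list alone. Without any one of 7 of the 8 libraries the adjusted p of the anti-apoptotic list in KMS12PE was above 0.05. It was 0.0547 without clone C replicate 3 and 0.296 without parental replicate 1, and 0.0566 without clone A replicate 1, 0.0632 without clone A replicate 3, 0.0761 without clone C replicate 1, 0.110 without clone D replicate 3 and 0.0553 without parental replicate 3.

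The series asks which other treatments the clones withstand, so the targets of myeloma immunotherapy and of lenalidomide were examined. CD38, the target of daratumumab, was nearly lost in 1 KMS27 clone. From 109 ± 3.9 CPM in the parental population it went to 2.54 CPM in clone C5 (log2FC -5.42, adjusted p = 1.19e-06). Its log2FC was -0.49 in B5 (adjusted p = 0.0236) and -0.30 in C1 (adjusted p = 0.117). With the 3 clones taken as 1 group of 6 libraries its adjusted p was 0.602. In KMS12PE CD38 had log2FC 0.40 (adjusted p = 0.0829, and 0.000517 with replicate number as a block). The responses of the lines differed for CD38 (adjusted p = 1.74e-07). TNFRSF17, which encodes BCMA, had log2FC 0.06 in KMS27 (adjusted p = 0.774). In KMS12PE it had 0.42 (adjusted p = 0.0689, and 0.000573 with the block), and clone D had 1.31 (adjusted p = 0.000159). SLAMF7, the target of elotuzumab, had log2FC -0.33 in KMS27 (adjusted p = 0.0537) and -0.22 in KMS12PE (adjusted p = 0.721). GPRC5D, listed in KMS12PE alone, stood at 1.33 ± 0.10 CPM and 1.16 ± 0.59 CPM. CRBN, the receptor of lenalidomide, its substrates IKZF1 and IKZF3, and CCND1, the gene that t(11;14) activates, passed the threshold in neither line. As a list the 13 immune synapse ligands of KMS12PE lay lower (median log2FC -0.23, adjusted p = 0.00715, and adjusted p = 0.739 with an estimated correlation), with 2 genes lower over all genes and 5 when adjusted over the list alone. By clone the adjusted p was 0.174 in A, 0.00109 in C and 0.103 in D. CD48, a ligand of the natural killer receptor 2B4, went from 135 ± 0.45 CPM to 91.1 ± 11 CPM (log2FC -0.58, adjusted p = 0.0366) and is one of them. Its adjusted p was 0.0840 without clone A replicate 3, 0.0777 without clone C replicate 3, 0.276 without parental replicate 3 and 0.279 without parental replicate 1. The list's was 0.0553 without parental replicate 3. The responses differed for this list (adjusted p = 0.0119, and adjusted p = 0.444 with an estimated correlation). In KMS27 it had 5 genes higher and 3 lower, with the same counts when adjusted over the list alone (adjusted p = 0.594).

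Among the genes that changed most in all 3 KMS27 clones, the chemokine receptor CCR7 rose from 3.17 ± 0.18 CPM to 55.5 ± 45 CPM (adjusted p = 9.59e-06) and IL2RB, a chain of the interleukin-2 receptor, from 1.66 ± 0.42 CPM to 21.7 ± 2.7 CPM (log2FC 3.69, adjusted p = 6.0e-06). The secreted matrix protein SPARC had 2 counts over the parental libraries and was 50.9-fold higher in clone B5 (95% interval 13.7 to 428), 131-fold in C1 (36.0 to 1085) and 162-fold in C5 (44.6 to 1346). The cytokine IL32 fell from 697 ± 102 CPM to 16.2 ± 4.2 CPM (adjusted p = 2.97e-06) and TRIM44 from 134 ± 2.0 CPM to 6.62 ± 5.2 CPM (log2FC -4.92, adjusted p = 2.16e-08). PLA2G16, a phospholipase, had 676 parental counts and 0 in clones B5 and C5, at least 181-fold and 232-fold lower, with log2FC -3.97 in C1. In all, 3631 of 14088 genes passed (1836 higher and 1795 lower, of which 422 and 595 by at least 2-fold), and 1160 passed in each of the 3 clones (634 higher and 526 lower). Without parental replicate 1 these counts were 1285 and 429, and without parental replicate 2 they were 1521 and 503. Without clone B5 replicate 1 they were 5825 and 1968, and without clone C5 replicate 2 they were 2413 and 566. The second count was also 544 without clone C1 replicate 1, 751 without clone C1 replicate 2 and 576 without clone C5 replicate 1. All p-values here measure the spread between the 2 libraries of a population, which may be technical only, since the labels do not say that the libraries come from separate cultures. With the clone rather than the library as the unit, 1032 genes passed with the libraries of each clone summed and 501 with the population as a random block. In the summed fit the 2 parental libraries stayed separate, so its error mixes the spread between libraries with that between clones. With clone identity ignored 1497 passed, in a fit that treats the 6 clone libraries as independent replicates.

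In KMS12PE a few genes fell far in all 3 clones, to different depths. POU2AF1, a coactivator of octamer factors in B cells, stood at 34.8 ± 0.75 CPM in the parental population, fell by 3.03 on the log2 scale in clone A and by 2.80 in clone C, and had 0 counts against 419 in clone D, at least 204-fold lower. The tetraspanin CD53 had log2FC -1.77 in clone A and -3.40 in clone C and was at least 83.6-fold lower in clone D. CD44, the hyaluronan receptor, had log2FC -5.75 in A, -1.83 in C and 1 count against 157 in D, 229-fold lower (95% interval 40.5 to 9094). ASS1, which makes arginine, fell from 79.7 ± 53 CPM to 13.1 ± 3.0 CPM (log2FC -2.64, adjusted p = 0.00295). These 4 genes were below both parental libraries in 6 of 6 clone libraries and passed without each library in turn. B cell genes as a list did not pass camera (8 genes, median log2FC -0.09, adjusted p = 0.259), with 1 higher and 1 lower, and the same counts when adjusted over the list alone. By fry the list passed as lower (adjusted p = 6.98e-05). FADS1, a fatty acid desaturase, went from 201 ± 4.8 CPM to 140 ± 7.3 CPM (log2FC -0.52, adjusted p = 0.00505). The phosphatase PTPRK, named after its values were seen, the protease ADAM17 (log2FC 0.61, adjusted p = 0.00555) and the adhesion molecule CADM1 (log2FC 2.88, adjusted p = 0.00223) were the 3 genes higher in all 3 clones. Without parental replicate 3 the adjusted p was 0.0868 for ADAM17, 0.0578 for CADM1 and 0.0629 for FADS1. Without parental replicate 1 it was 0.0808 for ADAM17 and 0.0920 for FADS1. In all, 181 of 12279 genes passed (44 higher and 137 lower) and 8 in each of the 3 clones (3 higher and 5 lower). In KMS12PE libraries with 1 replicate number resembled each other across populations, and with replicate number as a block these counts were 798 and 82. The count of 181 was 44 without parental replicate 3 and 49 without parental replicate 1. It was 95 without clone A replicate 3, 99 without clone A replicate 1, 104 without clone C replicate 1 and 109 without clone C replicate 3. The count of 8 was 2 or 3 without any one of those 6 libraries. With the clone as the unit, edgeR on clone sums against the 2 parental libraries and limma-voom with the population as a random block each called 0 genes. At an unadjusted p under 0.05 they had 550 and 307 genes. A fit in edgeR with clone identity ignored, where libraries count as independent, also called 0 genes, with 587 at an unadjusted p under 0.05.

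Ribosomal protein genes, the structural parts of the ribosome, were slightly lower in KMS12PE (72 genes, median log2FC -0.14, adjusted p = 3.48e-06, and adjusted p = 0.987 with an estimated correlation), with 0 genes called over all genes and 0 when adjusted over the list alone, and 13 lower with the block. In KMS27 the list had a like median of -0.13 (adjusted p = 0.169), with 5 genes lower and 0 higher, and 0 when adjusted over the list alone. By clone it was -0.19 in B5 (adjusted p = 0.0244), 0.19 in C1 (adjusted p = 0.0792) and -0.36 in C5 (adjusted p = 3.75e-05). The difference between the lines had adjusted p = 0.974, so the fall is not shown to be particular to KMS12PE. The epithelial-mesenchymal and matrix list was lower (9 genes, median log2FC -0.21, adjusted p = 0.0323, and adjusted p = 0.739 with an estimated correlation), with 1 gene lower and 3 when adjusted over the list alone. That gene, the matrix protein FN1, had log2FC -0.75 in clone A, 1.06 in clone C and -2.41 in clone D. By clone the list had adjusted p = 0.122 in A, 0.968 in C and 0.0214 in D. The T and NK list was lower too (5 genes, median log2FC -0.47, adjusted p = 0.0456, 0.801 with an estimated correlation and 0.0884 with the block), with 1 gene lower and 2 when adjusted over the list alone, and it passed in 0 of the 3 clones taken singly. Both lists missed the threshold without clone A replicate 3 (0.0781 and 0.0632), clone C replicate 3 (0.0547 for both) and clone D replicate 3 (0.0501 for both). The matrix list also missed it without parental replicate 1 (0.0790), and the T and NK list without clone C replicate 1 (0.0761), clone D replicate 1 (0.0551) and parental replicate 3 (0.753). FN1 had adjusted p = 0.0518 without parental replicate 3 and 0.0603 without parental replicate 1.

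The clones of 1 line were not alike. The transcription factor ETS1, chosen after its values were seen, had 1638 parental counts and 1 count in clone D, with log2FC -0.52 in clone A and 0.19 in clone C. The long noncoding RNA AFAP1-AS1 had log2FC -5.32 in clone A, -4.74 in clone C and 2.98 in clone D. ITGA6, a laminin receptor, had log2FC 2.18 in clone D, 0.03 in A and 0.12 in C. Setting each population against the other 3 gave, in KMS12PE, 233 genes for clone A, 473 for clone C, 1206 for clone D and 181 for the parental cells. With replicate number as a block these were 1020, 1486, 3091 and 798. In KMS27 it gave 1823 for clone B5, 1537 for C1, 1093 for C5 and 3631 for the parental cells. Each clone count includes its difference from the parental cells. The parental count divided by the largest clone count was 0.150 in KMS12PE, where that clone was D, and 1.99 in KMS27. The first was 0.155 with every library thinned to the smallest total, 0.258 with the block, 0.0459 without parental replicate 3, 0.0473 without parental replicate 1, 0.234 without clone D replicate 1 and 0.286 without clone D replicate 3. The second was 1.18 without parental replicate 1 and 1.13 without clone B5 replicate 2. Among the 3 clones 1009 genes differed in KMS12PE and 1933 in KMS27. The KMS12PE count was 3208 with the block, 657 without clone D replicate 3, 671 without clone C replicate 1 and 672 without clone C replicate 3. The KMS27 count was 1266 without parental replicate 2, 4587 and 4104 without replicates 1 and 2 of clone B5, 629 and 860 without those of C1, and 621 and 602 without those of C5.

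**Figure D2:**
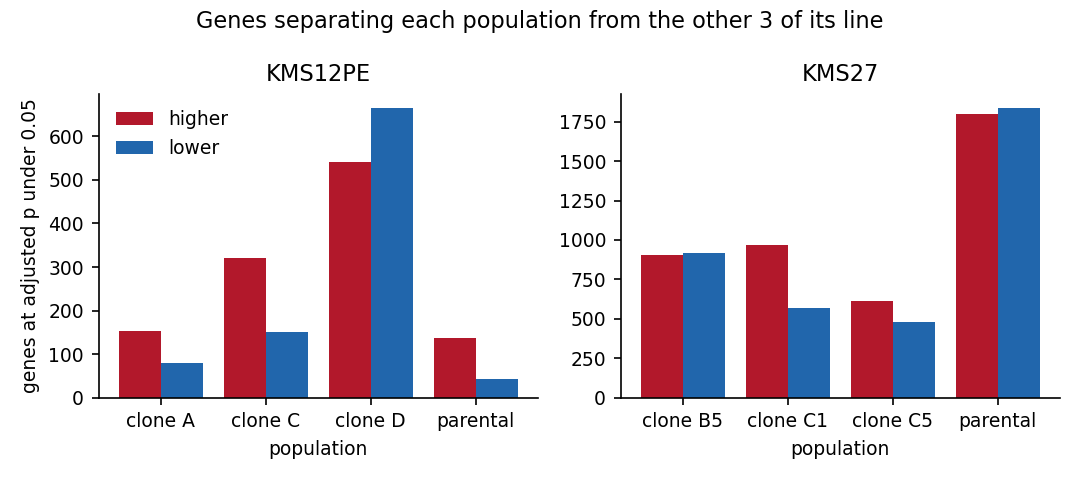
Genes at an adjusted p under 0.05 (y axis, number of genes) that separate each population (x axis) from the other 3 of its line, higher (red) and lower (blue) in that population. The parental population has the fewest genes in KMS12PE, 181, and the most in KMS27, 3631, and the y axes of the panels differ.

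Whole chromosomes moved together in KMS27. Genes of chromosome X had a median log2FC of 0.56 in clone B5, 0.59 in C1 and 0.53 in C5, and 264 of 451 were higher and 11 lower in the mean of the clones. Chromosome 11 was lower (medians -0.59, -0.36 and -0.38), with 354 of 672 genes lower, and chromosome 4 was lower (-0.32, -0.31 and -0.30). Chromosome 8 was higher (0.41, 0.19 and 0.16) and so was chromosome 6 (0.15, 0.14 and 0.18), where 150 of 634 genes were higher. In these 5 chromosomes 1202 of 2620 genes passed (45.9%), against 2429 of the 11468 other genes tested (21.2%). Those others include genes with no matched position. BTK, POLA1 and NSDHL lie on X, TRIM44, SYVN1 and PLA2G16 on 11, CD38, JCHAIN and CXCL10 on 4, CCNE2 and BLK on 8, and TAP1, HLA-B and most class II genes on 6, and their changes include such shifts. The log2FC of CD38 in clone C1 (-0.30) was about as large as the median of its chromosome there (-0.31), and in B5 it was larger (-0.49 against -0.32). Of 69 pairs of clone and chromosome 24 passed, and 12 passed with an estimated correlation. With that correlation chromosomes 4, 11 and X passed in all 3 clones. Chromosome 8 then passed in B5 alone (adjusted p = 0.0429, 0.182 in C1 and 0.231 in C5) and chromosome 6 in C5 alone (adjusted p = 0.0414, and 0.0702 in B5 and in C1). In KMS12PE 1 of 69 passed, chromosome 13 in clone D (median log2FC 0.18), and 0 with an estimated correlation. That count was 3 with the block, 3 without clone C replicate 1 and 5 without clone C replicate 3. Shorter stretches stood out in KMS12PE, as values without a test. In clone C all 56 genes of chromosome 17 between 80 Mb and its end lay lower, with a median log2FC of -0.98, against 0.07 in clones A and D. Between 0 and 20 Mb of chromosome 2 the medians were 0.28 in clone A, 0.55 in C and 0.00 in D, and between 20 and 40 Mb they were 0.26, 0.43 and 0.01. ADAM17 lies in the first of these stretches of chromosome 2.

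**Figure D3:**
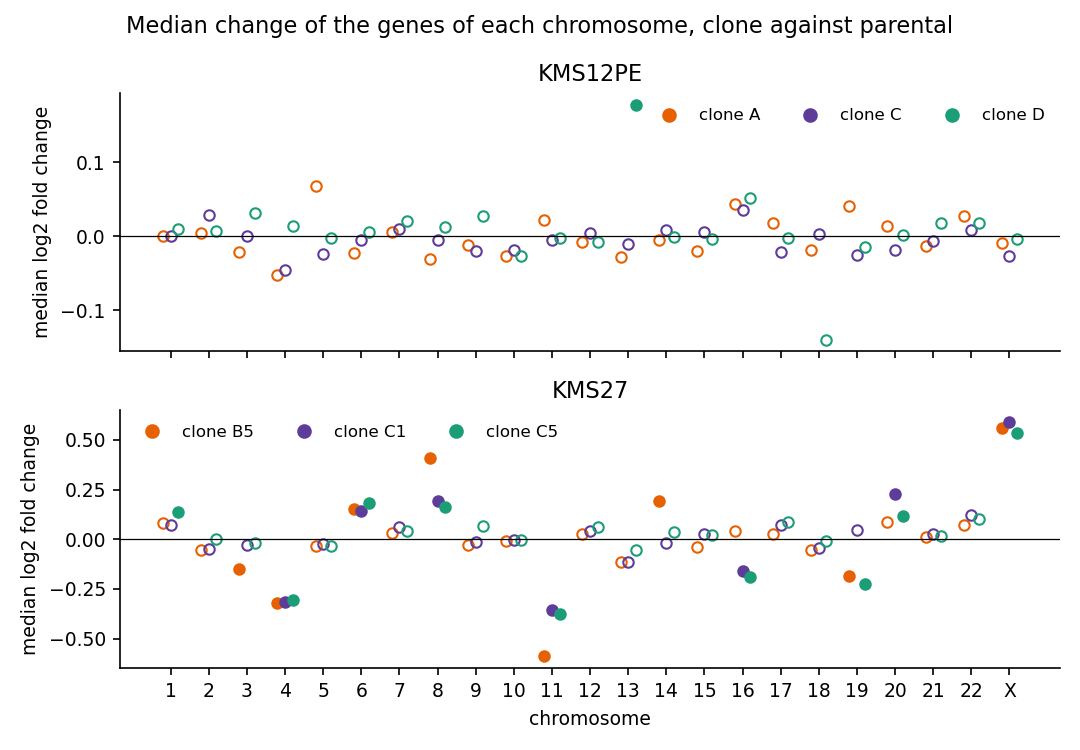
Median log2 fold change of the genes of each chromosome (y axis) in each clone against parental, by chromosome (x axis). Filled points passed the test at an adjusted p under 0.05 and open points did not, and X reaches 0.53 to 0.59 in the 3 KMS27 clones, while the y axes of the panels differ.

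Genes that changed in both lines were counted next. Of 11353 genes tested in both, 9 were higher in both (4.67 expected if the lists were independent, Fisher's exact test, 2-sided, p = 0.0424). The genes lower in both numbered 32 (12.6 expected, Fisher's exact test, p = 3.39e-07). Opposite changes were 6 genes higher in KMS12PE and lower in KMS27 (4.21 expected, Fisher's exact test, p = 0.304) and 20 lower in KMS12PE and higher in KMS27 (14.0 expected, Fisher's exact test, p = 0.110). With replicate number as a block in KMS12PE 50 were higher in both (37.1 expected, Fisher's exact test, p = 0.0250) and 82 lower (49.8 expected, Fisher's exact test, p = 4.45e-06). HERPUD1 was among the 32 lower genes. So was JCHAIN, which joins immunoglobulin units (899.6 ± 158 CPM to 601 ± 201 CPM in KMS12PE, 5742 ± 1057 CPM to 3333 ± 1326 CPM in KMS27). CCR2, a chemokine receptor, was lower too (57.2 ± 2.5 CPM to 22 ± 19 CPM, and 10.1 ± 1.7 CPM to 4.23 ± 3.3 CPM). RUNX1, a transcription factor, was among the higher ones. In KMS12PE JCHAIN passed at 0.0308 and gave 0.364 without parental replicate 3, 0.0586 without parental replicate 1, 0.0968 without clone A replicate 1, 0.0825 without clone A replicate 3 and 0.0528 without clone C replicate 3. RUNX1 passed at 0.00537 and gave 0.0835 and 0.0904 without parental replicates 3 and 1. The 41 shared genes were 10 without KMS12PE parental replicate 3 and 14 without KMS12PE parental replicate 1. They were 22 and 19 without replicates 1 and 3 of clone A, 23 and 22 without those of clone C, and 20 and 18 without KMS27 parental replicates 1 and 2. Genes that passed in all 3 clones of both lines numbered 0, with 0.138 expected in each direction. Across genes the log2 fold changes of the lines had a correlation of -0.0014, and genes are not independent replicates. The response itself differed between the lines for 1645 of 11623 genes (2535 with replicate number as a block). That count was 978 without KMS12PE parental replicate 1, 1091 without KMS12PE parental replicate 3 and 1017 without KMS27 parental replicate 1. CD53 went opposite ways, with log2FC 1.63 in KMS27 (adjusted p = 2.57e-08 for the difference).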

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

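The tests of the chromosome X windows, of the class II genes against their window, of B cells or macrophages, of the scaling, of depth and of single libraries, and the wording of the test of noise between libraries, were chosen or written only after the results were seen, and the length measure and the reading of the test within replicate numbers were changed after a first output.

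The response to resistance differed between the cell lines for 1645 genes, tested directly as a difference of differences, which is why these results are set out here. By list the adjusted p of the difference was 5.59e-20 for MHC class II, 3.22e-08 for the unfolded protein response, 0.00220 for cholesterol synthesis, 8.11e-05 for S-phase genes, 1.08e-05 for G2/M genes, 0.0119 for immune synapse ligands, 0.00301 for B cell genes, 0.00216 for plasma cell genes and 0.0390 for adhesion and homing. With an estimated correlation these were 0.133 to 0.561. By gene it was 3.02e-05 for BCL2L11, 4.55e-05 for PMAIP1, 1.74e-07 for CD38, 8.53e-09 for PLA2G16, 2.57e-08 for CD53, 5.63e-08 for AFAP1-AS1 and for ARHGEF3, 8.70e-08 for WDR35 and 1.04e-07 for CORO2A, and another 93 named genes differed too. ARHGEF3, which activates the GTPase RHOA, had log2FC 2.95 in KMS27, while in KMS12PE clone D it had 2 counts against 123, 89.6-fold lower (95% interval 24.3 to 748). WDR35, a part of the ciliary transport machinery, had log2FC -2.65 in KMS27 and 0.49 in KMS12PE, and the actin regulator CORO2A had 1.96 and -1.79. In KMS12PE CORO2A was at least 16-fold lower in clone D alone, at 1.37 CPM against 26.4 in the parental cells. The lines differ in depth, in replicate numbers and in founder cells, and none of these was separated from the line.

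The shifts of whole chromosomes in KMS27 were weighed first. Removing the trend of the fold changes on GC content and transcript length left the smallest chromosome X median of the 3 clones at 0.541, over the 88.7% of genes that could be matched, which argues against those biases as the whole source. The 2 libraries of a population differed in their X median by at most 0.0747, far below the smallest clone shift, which argues against noise between such libraries. Differences of culture or batch shared by both libraries of a population were not tested and stay open. All 7 of the 20-Mb windows of X had medians above 0.2 in all 3 clones (0.377 to 0.723). That is consistent with a change carried along whole chromosome X, such as a changed number of copies, but copy number was not measured here, and a parental population that had lost such copies after the clones were founded would look alike. Regulation of the whole chromosome stays open.

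The rise of MHC class II genes in KMS27 was weighed second. Of the 16 genes 11 lie in 1 window of chromosome 6, which was itself higher, yet the median of these 11 exceeded that of the other genes of the window by at least 2.33 log2 in each clone (the others had medians of 0.30, 0.22 and 0.33), which argues against the chromosome as the source for them. The other 5 lie on other chromosomes, and of those CD74 and CIITA rose by 1.74 and 1.88, RFX5 by 0.34 and IFI30 by 0.27, while CTSS had -0.05. B cells or macrophages mixed into the clones would bring their other abundant transcripts. The 5 such genes listed rose by a median of 0.0157% of the rise of HLA-DRA (highest 0.204%), and CD37 fell. In the clones CD79B stood at 4.35 CPM, MS4A1 at 3.29 (9.46 in clone C5), CD68 at 0.465 and CD79A at 0.349, against 1663 for HLA-DRA, which argues against such cells as the source, although 5 genes are few. The TMM factors of the KMS27 libraries lay between 0.928 and 1.09, a narrow range that argues against a few abundant genes acting through the scaling. Under 3 other scalings the smallest list median was 2.66, which these factors nearly fixed in advance. A regulatory change shared by the clones, or one present in the founder cells, may underlie the rise of class II genes and was not tested.

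The fall of ribosomal protein genes in KMS12PE was weighed last. None of 10000 random lists matched on expression and transcript length had a median as low (percentile 0 for gene length bias, lowest random median -0.09). Matched genes were lower too, by less (median of the random medians -0.0435), at a median of 9.30 log2 CPM against 9.65. Each random list was drawn gene by gene, so its spread leaves out any shared movement of ribosomal protein genes, and the percentile alone cannot decide. With every library thinned to the smallest total the median was -0.14, which argues against depth. With each library left out in turn the median closest to 0 was -0.0940, without clone D replicate 3 (adjusted p = 0.0116), which argues against 1 library that differs from the rest as the whole source. Every population holds both replicate numbers, so an offset shared by all populations cancels, and a fit with replicate number as a block cannot test an effect that differs between clones and parental cells. Within each replicate number, all 6 of the differences between a clone library and the parental library with its number lay below 0, but clone A replicate 1 lay at -0.0044 with a standard error of 0.015. The test written beforehand asked only for 6 values below 0 and ignored that error. The medians were -0.14, -0.28 and -0.32 in replicate 3 and -0.0044, -0.07 and -0.05 in replicate 1, so differences tied to the replicate number stay open, with 1 parental library per number. Reads shared with ribosomal pseudogenes were not tested. A lower output of ribosomal protein genes in the clones, or a parental population that had changed since the clones were founded, stays open as a hypothesis.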

How the results depend on the processing

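The alternatives for the chromosome shifts and the fit without shifted chromosomes were chosen after the results were seen, and the others were planned. Of 29 named genes called in KMS12PE 0 passed under every setting, since none passed with the clone as the unit, and 8 passed without each library in turn. Of 145 in KMS27 48 passed under every setting and 82 without each library. Of the lists called, 1 of 7 in KMS12PE and 5 of 6 in KMS27 passed without each library. In sign, 2 genes of KMS12PE reversed. AFAP1-AS1 went to 1.38 with clone identity ignored and to 1.38 with clone sums, since clone D outweighs the others in a mean of counts, and FN1 went to 0.16 without clone D, the clone with its largest fall.

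With a 2-fold threshold, 101 genes passed in KMS12PE and 1017 in KMS27, and 395 in all 3 KMS27 clones. With clone identity ignored, with clone sums and with a random block 0, 0 and 0 genes passed in KMS12PE (587, 550 and 307 at an unadjusted p under 0.05) and 1497, 1032 and 501 in KMS27, fits that count the spread between clones as error. Lists were tested without the random block, so for them that setting repeats the test with clone identity ignored, with libraries as replicates. That test and clone sums each dropped 3 of the 7 KMS12PE lists. These were the anti-apoptotic (adjusted p = 0.0937 and 0.141), the matrix (0.0937 and 0.141) and the T and NK list (0.320 and 0.336). Both called the immunotherapy antigens and G2/M genes of KMS12PE. In KMS27 the test with clone identity ignored dropped cholesterol synthesis (0.0539), as did the stricter filter (0.0581). Without the genes of chromosomes 4, 6, 8, 11 and X 2126 passed in KMS27, with fewer genes tested. In KMS12PE DESeq2 called 13 genes in all 3 clones and thinned counts 4, and the cause was not tested. The overlap of genes called in all 3 clones of each line was 0.

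With replicate number as a block KMS12PE gave 798 genes, 82 in all 3 clones, 3208 among clones, a parental ratio of 0.258 and 3 chromosome shifts. KMS27 gave 2965 among clones, and 2535 genes differed between the lines. With the block in KMS12PE 50 genes were higher and 82 lower in both lines. The block also called the immunotherapy antigens (adjusted p = 0.0382) and the G2/M list (0.0382) in KMS12PE, dropped its T and NK list (0.0884), and changed the call of no other list there.

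With an estimated correlation 0 lists passed in KMS12PE and 0 in KMS27, and 0 and 12 chromosome shifts. By fry none of the 7 lists called in KMS12PE passed (adjusted p 0.0502 to 0.526), and B cell genes did (6.98e-05, lower). In KMS27 fry called class II (0.00110), unfolded protein response (0.00396), G2/M (0.00256), S-phase (0.0276) and plasma cell genes (0.0185), but not cholesterol synthesis (0.203). It also called MAPK output (0.000334), matrix (0.000560) and anti-apoptotic genes (0.00147), all higher. B cell genes were called as lower (0.0132), although their median log2FC was 0.27, with 4 higher and 4 lower. With library totals alone KMS12PE had 3 chromosome shifts and with the stricter filter 6, and thinning dropped its anti-apoptotic (0.101) and T and NK lists (0.0731). Leaving out a clone dropped cholesterol synthesis (0.301) without clone A. Without clone C the anti-apoptotic (0.161), unfolded protein response (0.0883), immune synapse (0.0574) and T and NK lists (0.254) were dropped, and without clone D the anti-apoptotic (0.152), matrix (0.587) and T and NK lists (0.167). In KMS27 cholesterol synthesis (0.340) and G2/M genes (0.0692) were dropped without clone B5 and plasma cell genes (0.0608) without C5. Without C1 histone (0.00103) and ribosomal protein genes (0.000979) were called, and without C5 interferon-stimulated (0.000216) and MAPK output genes (0.0305). Also in KMS27, library totals alone called interferon-stimulated (0.0319) and ribosomal protein genes (0.0389), both lower. Interferon-stimulated genes were also called without immunoglobulin genes (0.04998), histone genes with the block (0.0457), and MAPK output genes without the shifted chromosomes (0.00522). The cause was not tested.

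Leaving out each library in turn gave 44 (parental replicate 3) to 186 genes in KMS12PE, 2 to 10 in all 3 clones, 657 to 898 among clones, ratios of 0.0459 to 0.286, 2 to 8 lists and 1 to 5 chromosome shifts. KMS27 gave 1285 (parental replicate 1) to 5825 (clone B5 replicate 1) genes, 429 to 1968 in all 3 clones, 602 to 4587 among clones and ratios of 1.13 to 2.65. The 2 libraries of clone B5 differed most (chi-square per degree of freedom 58.0), and the biological coefficient of variation, 14.3% with all libraries, was 10.1% without either one. Between the lines 978 to 2283 genes differed and 10 to 45 were shared. With 2 parental libraries per line, most simulated changes of 1.5-fold were missed (44.8% recovered in KMS12PE and 26.9% in KMS27). The KMS12PE parental libraries held 5831289 and 6340658 counts, and recovery of genes near the floor was not measured.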

Other observations

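The zinc finger test was chosen after the values were seen, and in the test of adjacent genes overlapping genes were taken out after a first output of 4 pairs.

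Clones nearly lost genes that the parental cells expressed, some in 1 clone and others in several. Counting genes at 5 CPM or more in the parental cells, 35 were at least 16-fold lower in KMS12PE clone D, 8 in clone A and 5 in clone C, and 34, 9 and 30 in KMS27 clones B5, C1 and C5. Together these are 121 cases of gene and clone, over 89 genes. Clones B5 and C5 shared many of them, such as PLA2G16 and ANKS6, with 0 counts in both against 676 and 318. KMS12PE clone D had 1 count of ETS1 against 1638, 0 of KCNMA1, a potassium channel, against 246, 0 of PRAME, a cancer-testis antigen, against 144 and 0 of MYCN against 64. Its IL2RB had 2 counts against 113, while IL2RB rose in KMS27. The ARMCX3 gene on X had 14 counts in clone A and 0 in clone C against 200, with its neighbour ARMCX6 at 2 and 1 against 68. In KMS27 4 genes were at least 16-fold lower in all 3 clones, IL32, CD37, UBASH3B, a phosphatase that restrains receptor signalling (52.1 ± 2.3 to 0.650 ± 0.18 CPM), and CD163L1 (22.8 ± 3.7 to 0.551 ± 0.56 CPM).

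Loss of a stretch of the genome that holds several genes would place such genes side by side. Among the 121 cases 3 pairs were adjacent, against 1 at the 95th percentile of 10000 random draws, so small losses of a stretch of the genome may explain a few, although 2 of the 3 pairs are ARMCX3 and ARMCX6 counted in 2 clones and neighbours can share regulation. The remaining pair lies on chromosome 22 in KMS12PE clone D. There PRAME lies beside the immunoglobulin lambda genes IGLL5, with 0 counts against 596, and IGLC1, with 1 against 493. For 114 of the 121 cases no neighbour was as low, which leaves single-gene loss and silencing open.

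Zinc finger genes seemed lower in the KMS27 clones, with 48 of 206 lower and 16 higher on chromosome 19. The other 222, on other chromosomes or with no matched position, had 31 lower and 29 higher, at a median log2FC of 0.04, which argues against a fall of the whole family. As a family they did not pass (camera, unadjusted p = 0.179). The other genes of chromosome 19 had a like median (-0.15 against -0.14), but 99 of those 705 others were lower, a smaller share (14.0% against 23.3%, Fisher's exact test across genes, p = 0.00243). A fall particular to the zinc finger genes of chromosome 19 was left open. Among 58 families of symbols sharing a prefix in KMS27, set up after the data were seen, 3 passed at the preset correlation and 0 with an estimated one: HLA (median log2FC 2.41), histone (0.45) and SEC genes (-0.23).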
